A study of Zea mays with 8 samples.

How the data were processed

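RNA was sequenced from immature ears of maize in 8 libraries, 2 in each of 4 groups: the inbred parents B73 and Mo17, their wild-type hybrid (WTF1) and a hybrid homozygous for a mutation in mop1 (mop1F1). Groups and replicate numbers came from the sample titles. One B73 library is numbered 2 in its title and 1 in the name of its count table, and the title was followed. The labels do not say whether the 2 libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may be partly technical.

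The deposited files hold whole-number counts per gene ID, 1 library per file, with 39498 gene IDs and 5 summary rows as htseq-count writes them. FastQC, Trimmomatic, HISAT2, HTSeq and DESeq2 are named, without versions, in the submitters' processing notes. Per the names the authors gave the deposited count tables, the Mo17 libraries were mapped to Mo17 and the other libraries to B73. Every gene ID carries the suffix RefGen_V4 in all files. The strand setting of the counting, the aligner options and the annotation release are not given in the sources used here, so overlapping and antisense genes cannot be told apart, and members of multigene families may share reads. Mapping to different genomes is confounded with the parent, and a hybrid mapped to B73 can lose reads of its Mo17 copies.

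None of the gene IDs matched the gene table used here (assembly Zm-B73-REFERENCE-NAM-5.0), which lists older identifiers of another style: 0 IDs were paired with a symbol. The 19 gene lists fixed before the data were examined, among them the genes of RNA-directed DNA methylation, were therefore not tested, and the mop1 gene itself is not reported here. No chromosome or coordinates are given for the same reason. The rule for genes named in the text allowed, without names, at most 2 IDs that rose and 2 that fell per comparison. They had to have an adjusted p below 0.05, a mean of at least 1 CPM in a compared group and no overlap between the libraries of the compared groups, and those with the largest log2 fold change were taken. The lists of genes of leaf, kernel and male tissue, planned as a check for other sources of RNA, could not be tested either.

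The total of counts over gene IDs was 18624989 and 17154254 in B73, 16582416 and 17293259 in Mo17, 11723096 and 26199577 in WTF1, and 23505695 and 26042879 in mop1F1, for replicates 1 and 2. One count corresponds to less than 0.1 CPM. A count of 0 allows up to 3 counts, which is between 0.115 and 0.256 CPM per library. Such limits cover counting error only, since no molecular identifiers were used to count. The summary rows were left out of library sizes and tests. As a share of all records, reads without a feature made up 3.64% to 5.79%, ambiguous reads 1.29% to 10.25%, reads of low alignment quality 1.76% to 9.35%, unaligned reads 2.00% to 6.11% and reads with several alignments 2.80% to 3.43%.

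Counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1): filterByExpr by group, TMM scaling, a group-means design and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. All 8 libraries entered one fit, which kept 24511 IDs and shared one estimate of the spread, because 2 libraries per group leave few degrees of freedom. The standard error of a log2 fold change was taken as its size divided by the square root of F. For the mid-parent, the B73 and Mo17 libraries with the same replicate number were thinned at random to the same total (seed 11) and added, which gave 2 mixed libraries whose pairing is arbitrary. They were fitted with the 4 hybrid libraries, and 24942 IDs were kept. CPM values of single IDs are counts scaled to the gene total of the library; the spread of replicates, the parental scale and the ratios to B73 used CPM with the TMM factors. Where both libraries of a group had 0 counts, the fold is a lower bound against 3 counts per library, and it assumes that the ID was in the gene set used for that group. IDs expressed differently in the parents were also placed on a scale from 0 (the Mo17 mean CPM) to 100% (the B73 mean CPM).

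Alternatives fixed before the data were examined were DESeq2 size factors, no filter and a filter of 1 CPM in 2 libraries, the DESeq2 1.42.0 Wald test (without the filter by group, with its own filtering), the replicate number as a block, a minimum log2 fold change of 1, fits of the compared groups alone, crossed and log-scale mid-parents, and leaving out each library. The fits were tested on simulated data with 200 changed IDs in each of 3 simulations per comparison. Each simulated ID had the same spread in all groups, whereas in the data the hybrid libraries varied more than the parental ones. Recovery and false calls therefore do not describe groups of unequal spread. For mop1F1 against WTF1, 81.8% of 16-fold changes, 20.9% of 4-fold changes and 0% of 2-fold changes were recovered over 24035 IDs, with 7.3 false calls per simulation. For WTF1 against the mid-parent, 84.8%, 14.4% and 1.0% were recovered, over 24231 IDs and with 4.7 false calls. For B73 against Mo17, 79.3%, 14.4% and 1.0% were recovered, over 24049 IDs and with 5.7 false calls. Over the 3 simulations, 22 of 226, 14 of 213 and 17 of 205 calls were false in these comparisons. Replicates of a group were not duplicates: the chi-square of their counts per ID was at least 10.9, where sampling noise alone gives a value near 1.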

Results

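Expression was measured by RNA sequencing of immature maize ears from the inbred lines B73 and Mo17, from their wild-type hybrid (WTF1) and from a hybrid homozygous for a mop1 mutation (mop1F1). The mop1 gene encodes an RNA-dependent RNA polymerase of the pathway that makes small RNAs for RNA-directed DNA methylation. The study concerned CHH methylation, how it is set up and kept, and its bearing on gene expression, per its title. The labels write the parents of the wild-type hybrid in the order Mo17/B73 and those of the mutant in the order B73/Mo17, with no further account of the crosses. Each group held 2 libraries with 11723096 to 26199577 counted reads. Genes are given by their IDs, because the sources used here did not pair them with names.

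The parental libraries were close replicates and the hybrid libraries were not. The biological coefficient of variation was 16.5% in B73 and 14.6% in Mo17 but 46.8% in WTF1 and 59.4% in mop1F1 (n = 2 each). Between the 2 libraries of a group, 1309 IDs in B73, 1752 in Mo17, 6511 in WTF1 and 6784 in mop1F1 differed more than 2-fold. In both hybrids, the libraries numbered 1 also had many reads assigned to no single gene: 9.70% of records were ambiguous in WTF1 replicate 1 and 10.25% in mop1F1 replicate 1, against 1.29% to 2.35% in the other 6 libraries. In log2 CPM, WTF1 and mop1F1 correlated at 0.938 between their libraries numbered 1 and at 0.94 between those numbered 2. Across numbers the correlation was 0.916 within WTF1 and 0.867 within mop1F1. Between the hybrids it was 0.887 (WTF1 replicate 1) and 0.931 (WTF1 replicate 2) across numbers. The spread within a hybrid thus includes any difference between the numbers. The groups separated as parents and hybrids, and the WTF1 and mop1F1 libraries did not form separate groups.

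**Figure D1:**
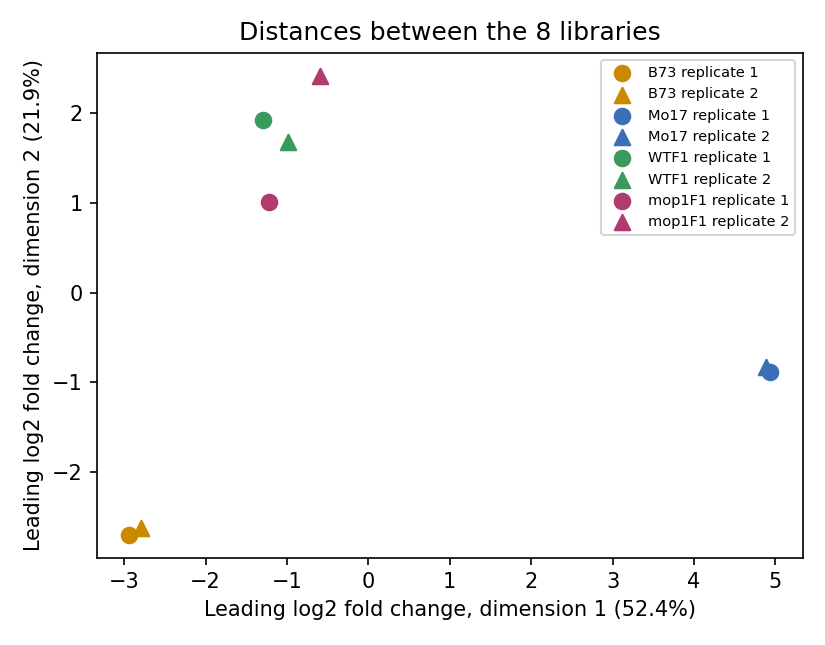
Multidimensional scaling of the 8 libraries on the leading log2 fold changes between them, with 1 point per library, circles for replicate 1 and triangles for replicate 2. The first dimension (52.4%) sets Mo17, near 4.9, apart from the other groups, and the second (21.9%) sets the hybrids, at 1.01 to 2.42, above B73, near -2.7.

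The mutant hybrid was compared with the wild-type hybrid, both mapped to B73. The order of the parents in the labels and any segment linked to the mutation differ along with the mutation and were not separated from it. Among 24511 IDs tested, 1 rose and 1 fell. Zm00001d025803.RefGen_V4 was nearly silent in the wild-type hybrid (0.223 ± 0.046 CPM, SD, n = 2) and reached 17.4 ± 0.369 CPM in mop1F1, a log2 fold change of 6.36 ± 0.53 (SE, edgeR quasi-likelihood test, adjusted p = 0.0449). It was also low in both parents, with at most 0.663 CPM in any of the 4 parental libraries. Zm00001d003267.RefGen_V4 fell from 176 ± 95.5 CPM in WTF1 to 1.88 ± 0.492 CPM in mop1F1, a log2 fold change of -6.48 ± 0.50 (SE, edgeR, adjusted p = 0.0449). In the parental libraries of Zm00001d003267.RefGen_V4 the level lay between 208.3 and 255.5 CPM. Without WTF1 replicate 1 or without WTF1 replicate 2, 1 ID was called, which was lower in mop1F1. Without mop1F1 replicate 2 it was 0 IDs (edgeR, 2298 at an unadjusted p below 0.05), and without mop1F1 replicate 1 it was 187 IDs, 12 higher and 175 lower.

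Within each replicate number the direction of both IDs was the same, which the rule of no overlap between the groups required of any named ID. For Zm00001d003267.RefGen_V4 the level was 244 CPM in WTF1 and 1.53 CPM in mop1F1 among the libraries numbered 1, and 109 against 2.23 CPM among those numbered 2. For Zm00001d025803.RefGen_V4 it was 0.256 against 17.1 CPM and 0.191 against 17.6 CPM. With a term for the 2 libraries rich in ambiguous reads, added after the data were seen, 0 IDs passed (edgeR, 822 at an unadjusted p below 0.05, adjusted p = 0.0684 for both IDs). A fit of the 4 hybrid libraries alone also called 0 IDs (edgeR, 170 at an unadjusted p below 0.05). With the replicate number as a block, 0 IDs passed as well (edgeR, adjusted p = 0.113 for Zm00001d025803.RefGen_V4 and 0.0803 for Zm00001d003267.RefGen_V4). Over all alternatives the log2 fold change of Zm00001d025803.RefGen_V4 lay between 6.09 and 6.54 and that of Zm00001d003267.RefGen_V4 between -6.98 and -5.63, with adjusted p from 1.9e-14 and 1.49e-39 (DESeq2) up to 1 (edgeR). At an unadjusted p below 0.05, 290 IDs were higher and 167 lower in mop1F1, 457 in all, where chance would give 1226. DESeq2 called 41 IDs, of which 28 were higher and 13 lower in mop1F1.

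**Figure D2:**
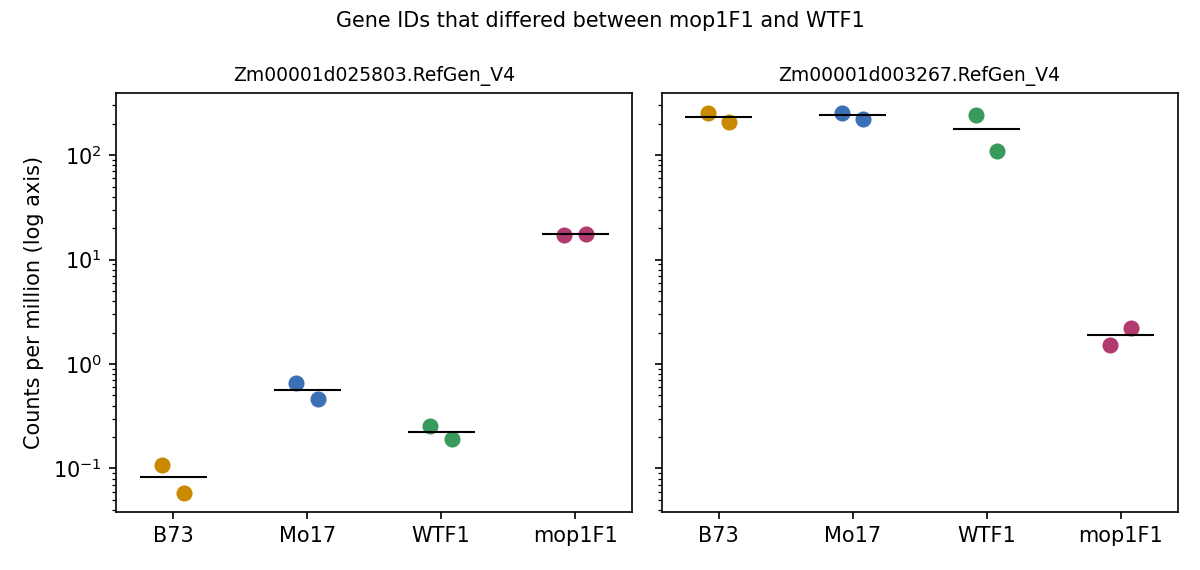
Expression in CPM, on a log axis, of the 2 IDs that differed between mop1F1 and WTF1, with 1 point per library and a line at the mean of each group. Zm00001d025803.RefGen_V4 stands at 17.1 and 17.6 CPM in mop1F1 and under 1 CPM elsewhere, and Zm00001d003267.RefGen_V4 stands at 1.53 and 2.23 CPM in mop1F1 and above 100 CPM elsewhere.

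The strongest differences between mop1F1 and WTF1 were not spread evenly along the gene ID numbers. Such numbers generally follow the order of gene models along the chromosomes, which was not checked here. An unadjusted p below 0.01 (edgeR) was found for 114 of the 24491 IDs scanned, where chance would give 245. Of these 114 IDs, 17 fell among the 200 tested IDs numbered from 3045 to 3422, where 0.93 would be found with even spacing. Of these 17 IDs, 16 were lower and 1 was higher in mop1F1. The called ID Zm00001d003267.RefGen_V4 was one of them. DESeq2 placed 8 of its 41 calls there, and all 8 were lower in mop1F1. This window was chosen because its count was the highest of all.

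**Figure D3:**
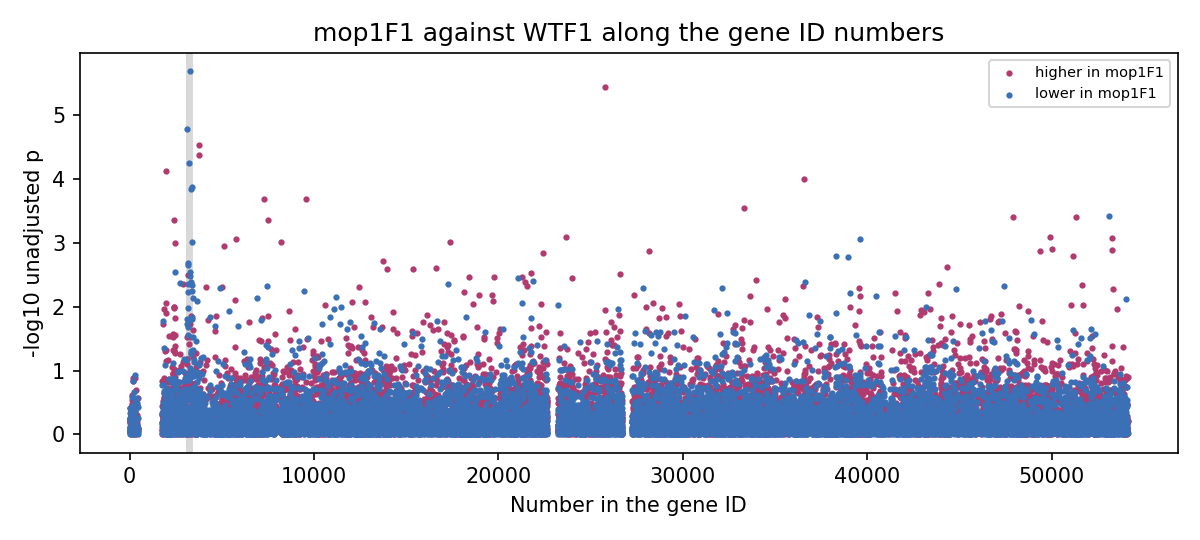
Unadjusted p of mop1F1 against WTF1, as -log10, for each tested ID against the number in its ID, coloured by direction. The grey band marks the IDs numbered 3045 to 3422, which hold 17 of the 114 IDs with p below 0.01.

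The inbred parents differed at 2561 of 24511 IDs (10.45%, edgeR quasi-likelihood test). B73 was higher at 1521 IDs and Mo17 at 1040. The parents fitted alone, without the larger spread of the hybrids, gave 9334 of 23444 IDs, 5072 higher and 4262 lower in B73. With the term for the 2 libraries rich in ambiguous reads, 4010 of the 24511 IDs were called. Leaving out 1 library lowered the 2561 IDs to 1062 and 1135 without B73 replicate 1 and 2, and to 1067 and 1089 without Mo17 replicate 1 and 2. Many of these IDs had no counts in a parent: 556 of the IDs higher in B73 had 0 counts in both Mo17 libraries, and 470 of those higher in Mo17 had 0 counts in both B73 libraries. A 0 can stand for absent expression or for an ID left out of the gene set or genome that a library was mapped to. All 173 tested IDs numbered 460 or lower were at 0 in both Mo17 libraries, compared with 745 (3.1%) of the other 24338 IDs, and 147 of them were among the IDs called higher in B73. Zm00001d000001.RefGen_V4, with 591 ± 145 CPM in B73 and 0 counts in Mo17 (edgeR, adjusted p = 0.000176), is one of these, and no fold is given for it. Zm00001d021300.RefGen_V4 had 456 ± 84.1 CPM in B73 and 0 counts in Mo17, at least 2576-fold higher (edgeR, adjusted p = 0.000377). In the other direction, Zm00001d013111.RefGen_V4 had 189 ± 112 CPM in Mo17 and 0 counts in B73, at least 1123-fold lower in B73 (edgeR, adjusted p = 0.000276), and Zm00001d043896.RefGen_V4 had 89.0 ± 6.65 CPM, at least 530-fold lower (edgeR, adjusted p = 0.000289; SD, n = 2 for each value). Of the called IDs, 965 higher in B73 and 570 higher in Mo17 were not at 0 in either parent. The IDs at 0 in both libraries of a parent were also dropped after the fit and the p-values adjusted anew. Then 682 IDs were higher in B73 and 379 in Mo17.

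**Figure D4:**
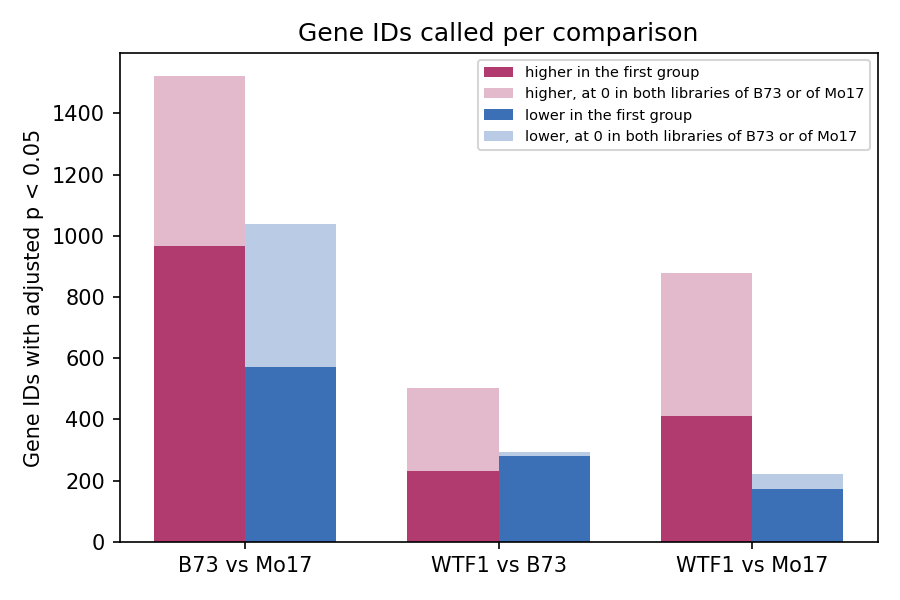
Number of IDs with an adjusted p below 0.05 (edgeR) in 3 comparisons, with bars for IDs higher and lower in the first group and the pale part for IDs at 0 in both libraries of B73 or of Mo17. The pale part makes up 556 of 1521 and 470 of 1040 IDs in B73 against Mo17, and 467 of the 879 IDs higher in WTF1 than in Mo17.

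The wild-type hybrid was called different from each parent at fewer IDs than the parents from each other. At an unadjusted p below 0.05 (edgeR) the numbers were closer: 5261 IDs against B73, 5153 against Mo17 and 5773 between the parents. The calls therefore do not measure how near the hybrid was to a parent. Against B73, 503 IDs were higher and 293 lower in WTF1. In a fit of WTF1 and B73 alone, 385 were higher and 440 lower, so the balance of directions depended on the fit. Against Mo17, 879 were higher and 223 lower. The 796 IDs against B73 became 83 and 113 without B73 replicate 1 and 2, 236 without WTF1 replicate 1 and 1023 without WTF1 replicate 2. The 1102 IDs against Mo17 became 454 and 455 without Mo17 replicate 1 and 2, 756 without WTF1 replicate 1 and 1737 without WTF1 replicate 2. Of the IDs higher in WTF1, 258 were at 0 in both B73 libraries in the first comparison and 464 were at 0 in both Mo17 libraries in the second. Zm00001d042113.RefGen_V4 (35 ± 30.7 CPM, at least 208-fold higher) and Zm00001d013111.RefGen_V4 (29.5 ± 2.29 CPM, at least 176-fold higher) rose against B73 (edgeR, adjusted p = 0.0092 and 0.004). Zm00001d049882.RefGen_V4 and Zm00001d002350.RefGen_V4, at 8.41 ± 0.262 and 6.83 ± 3.32 CPM in B73, had 0 counts in WTF1, at least 45-fold and 37-fold lower (edgeR, adjusted p = 0.0272 and 0.0381). With the replicate number as a block these 2 lower IDs no longer passed (edgeR, adjusted p = 0.0564 and 0.0645), while the 2 higher IDs did. Against B73, 3 of these 4 calls were lost without B73 replicate 1 or 2 (edgeR, adjusted p = 0.0676 and 0.0614 for Zm00001d042113.RefGen_V4, 0.217 and 0.202 for Zm00001d049882.RefGen_V4, 0.256 and 0.17 for Zm00001d002350.RefGen_V4). Both lower IDs were also lost without WTF1 replicate 1 (edgeR, adjusted p = 0.0748 and 0.106), and Zm00001d002350.RefGen_V4 without WTF1 replicate 2 (edgeR, adjusted p = 0.0753). Against Mo17, Zm00001d000339.RefGen_V4 (247 ± 223 CPM) and Zm00001d000300.RefGen_V4 (203 ± 74.5 CPM) were called higher in WTF1 (edgeR, adjusted p = 0.0195 and 0.000254), while Zm00001d015588.RefGen_V4 and Zm00001d023615.RefGen_V4 were at 20.8 ± 2.76 and 14.7 ± 1.19 CPM in Mo17 and at 0 counts in WTF1, at least 112-fold and 79-fold lower (edgeR, adjusted p = 0.00956 and 0.00955). Of these, Zm00001d000300.RefGen_V4 alone passed without any 1 library. Without Mo17 replicate 1 or 2, the adjusted p (edgeR) was 0.103 and 0.101 for Zm00001d000339.RefGen_V4, 0.0584 and 0.0679 for Zm00001d015588.RefGen_V4, and 0.084 and 0.0911 for Zm00001d023615.RefGen_V4, and it was 0.0661 for Zm00001d000339.RefGen_V4 without WTF1 replicate 1. The errors are SD with n = 2. Both IDs called higher than in Mo17 carry numbers of 460 or lower, as do 142 of the 879, so their 0 in Mo17 can stand for an ID left out and no fold is given. Among the called IDs not at 0 in either parent, 231 were higher and 282 lower than in B73, and 412 higher and 174 lower than in Mo17. The IDs at 0 in both libraries of a parent were also dropped after the fit and the p-values adjusted anew. Then 128 were higher and 144 lower than in B73, and 212 higher and 58 lower than in Mo17. With the term for the libraries rich in ambiguous reads, 1138 IDs were higher and 1363 lower than in B73, and 1190 higher and 576 lower than in Mo17.

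At IDs called different between the parents, most hybrid levels lay between the parental means. These IDs were picked for a parental difference, which makes such a place likely, so this does not describe other IDs. Over all tested IDs outside the numbers 3045 to 3422, 24.8% had both mop1F1 libraries beyond all parental libraries, on the same side. At the 965 IDs higher in B73 and not at 0 in either parent, the median level of WTF1 lay at 35.5% of the way from Mo17 to B73 (quartiles 12.5% and 60.3%; 37.0% and 29.4% in the 2 libraries), and that of mop1F1 at 39.1% (37.8% and 35.5%). At the 570 such IDs higher in Mo17, it lay at 68.0% in WTF1 (67.4% and 70.6%) and at 66.3% in mop1F1 (71.7% and 60.6%). In both sets the median of each hybrid library was therefore on the side of the parent with the lower level. Mo17 copies were read against B73 in the hybrids and against Mo17 in the parent, which could lower them in the hybrids.

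WTF1 was above both parents at 57 IDs and below both at 35, and mop1F1 was above both at 100 and below both at 46 (edgeR, both adjusted p values below 0.05). The 2 tests share the hybrid libraries. Simulated groups without any change, made for WTF1 alone, gave 0 such IDs in 3 runs. With no changed IDs few calls can arise, so these runs do not show how far shared libraries raise the overlap. Independent lists of the same lengths would share 18 IDs above and 2.7 below for WTF1, and 26.6 and 2.8 for mop1F1. With 2 libraries per group the hybrid libraries could not be split, so part of the excess may come from sharing them. The counts moved with single libraries. WTF1 lay outside both parents at 4 and 5 IDs without B73 replicate 1 and 2, at 11 without either Mo17 replicate, at 23 without WTF1 replicate 1 and at 422 (225 above and 197 below) without WTF1 replicate 2. For mop1F1 these were 7 and 12 IDs without B73 replicate 1 and 2, 16 and 17 without Mo17 replicate 1 and 2, 1086 (469 above and 617 below) without mop1F1 replicate 1 and 340 (292 above and 48 below) without mop1F1 replicate 2. With the term for the libraries rich in ambiguous reads, WTF1 was above both parents at 212 IDs and below both at 253, and mop1F1 at 377 and 309. The difference between the hybrids in these counts was not tested. In the fit of all 8 libraries, 32 above and 35 below for WTF1, and 67 above and 46 below for mop1F1, were not at 0 in either parent. The IDs at 0 in both libraries of a parent were also dropped after the fit and the p-values adjusted anew. Then 5 were above and 12 below for WTF1, and 26 above and 20 below for mop1F1.

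Deviation from additivity was tested against mixed libraries that hold equal shares of B73 and Mo17 reads. No ID was called as deviating from this arithmetic mid-parent in WTF1 or in mop1F1 (edgeR quasi-likelihood test, smallest adjusted p = 0.149 and 0.137). At an unadjusted p below 0.05 there were 2817 IDs in WTF1, 1544 higher and 1273 lower. In mop1F1 there were 2978, 1796 higher and 1182 lower. Chance would give 1247 of 24942 in each hybrid, both directions together, so some IDs may deviate without being called. Mapping was not separated from deviation: the Mo17 reads of the mixtures were mapped to Mo17, the hybrids to B73. An ID left out of the Mo17 gene set would also stand above the mixtures. With the IDs at 0 in both libraries of a parent dropped after the fit, 2256 of 23146 IDs remained below 0.05 in WTF1 and 2379 in mop1F1 (edgeR). Between the hybrids, 457 IDs were below this limit, under the 1226 of chance, so such chance numbers are a rough guide. DESeq2 called 933 IDs in WTF1, 521 higher and 412 lower, and 1019 in mop1F1, 610 higher and 409 lower. With the mid-parent on the log scale, edgeR called 1169 and 1485 IDs, of which 991 and 1278 were higher; this scale puts IDs that 1 parent alone expresses above the mid-parent.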

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

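The tests on the run of ID numbers against random placement, on the depth of the Mo17 libraries, on the split of the IDs at 0 in Mo17 by number, on the neighbours of IDs lower in the libraries numbered 1, on the number of IDs higher there and on library size were chosen after the results were seen.

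Some kinds of record that the counting step set aside, which no comparison used, stood above the highest parental library in some hybrid libraries, and the shares that did so are given first. Ambiguous reads made up 9.70% of records in WTF1 replicate 1 and 10.25% in mop1F1 replicate 1. Reads of low alignment quality made up 9.35% and 8.31% in WTF1 and 9.35% and 8.01% in mop1F1. Reads with several alignments made up 3.37% in WTF1 replicate 1, and 3.25% and 3.43% in mop1F1. Reads without a feature made up 5.79% in mop1F1 replicate 2. The others were not above the parents: ambiguous reads were 1.29% and 1.35% in the hybrid libraries numbered 2, reads without a feature 3.64% to 5.24% in the other 3 hybrid libraries, reads with several alignments 3.09% in WTF1 replicate 2, and unaligned reads 2.79% to 3.21% in the hybrids against up to 6.11% in Mo17.

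The libraries numbered 1 and 2 differed in part alike in the hybrids: at 2-fold or more, 1980 IDs were higher and 358 lower in number 1 in both groups, where 799 and 199 would coincide by independence, and 680 differed in opposite directions. Library size is argued against, because the totals of the mop1F1 libraries differed by only 1.11 times. Reads lost to overlaps of neighbouring gene models could only lower an ID and do not account for the 1980 IDs that were higher; for the lower ones the share with a neighbour of the same kind was 2.8%, between the median (1.7%) and the upper 5% limit (3.4%) of random sets, which leaves this open. Of the IDs higher in number 1, 25.8% had a neighbouring ID at 10 times their level or more, above the upper 5% limit (25.4%) of random sets matched on level, which was the bound set beforehand, so reads of a strongly expressed neighbour may contribute, but the excess over the median of random sets (24.1%) was 1.7 points. A difference in growth, harvest or library preparation between the numbers stays open and was not tested. The column headers give the numbers a shared prefix of unstated meaning. A difference in the counting was not tested either, since its strand setting and annotation release are not given. Reads without a feature made up 4.31% (WTF1) and 3.64% (mop1F1) of records in number 1, and 5.24% and 5.79% in number 2.

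The hybrids' deviation from the parents differed at 2 IDs, by the direct edgeR test of mop1F1 against WTF1: the log2 difference was -6.48 for Zm00001d003267.RefGen_V4 and 6.36 for Zm00001d025803.RefGen_V4. Both had an adjusted p of 0.0449 (edgeR) and passed with DESeq2. They did not pass in edgeR with the replicate block (adjusted p = 0.0803 and 0.113) or with the hybrids alone (0.802 for both). Neither hybrid had an ID called against the mid-parent.

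The run of IDs from 3045 to 3422 held 17 IDs with p below 0.01 in mop1F1 against WTF1, and no random placement reached more than 9 (permutation p = 1e-04, the smallest that 10000 placements can give). Windows of 50 and 100 IDs peaked at 7 and 10 IDs in the same stretch, against 6 and 7 in the highest of 2000 random placements. A stretch that varies between any libraries is argued against, since it held 0.95 times the even share in B73 against Mo17 and 0.78 times in WTF1 against the mid-parent, but 2.93 times in mop1F1 against the mid-parent. For a stretch that is B73 or Mo17 on both chromosomes, the change in mop1F1 should follow the parental difference across its IDs. The Spearman rho was -0.18 (permutation p = 0.013, where genes are not independent replicates), smaller in size than the bound set beforehand. What rho such a stretch would give in hybrids this variable was not measured, so the test cannot exclude it. A segment linked to the mutation and inherited from another background than both parents may be the source: 64.7% of the 17 IDs lay outside the parental range in mop1F1, over the 50% set beforehand, but so did 71.1% of the 97 such IDs elsewhere, so the test cannot tell such a segment from any other change, and a general loss of reads of a diverged haplotype also stays open, because the median log2 change of -0.099 lay past the bound of -0.1, above which such a loss was to be set aside, by less than its spread (95% bootstrap interval -0.163 to 0.031; random sets 0.009 to 0.089).

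Among all 2465 IDs with counts in B73 and 0 in both Mo17 libraries, 686 (27.8%) would have 10 counts or more in the smaller Mo17 library at the B73 level, so low depth may account for many of the zeros at low levels. For IDs with at least 1 CPM in B73 low depth is argued against: 567 of these 21635 IDs were at 0 in both Mo17 libraries, where counting at the B73 level with the spread of the noisiest group would give 0.0061, and the median log2 ratio of WTF1 to B73 over the 567 was -0.80, which decides nothing on the gene set. For the 148 IDs numbered 460 or lower it was -0.08 (95% bootstrap interval -0.13 to 0.03), close to the -0.01 of IDs expressed in both parents, which is what IDs left out of the gene set or genome used for Mo17 would give and which suggests that Mo17 copies were expressed in the hybrid. For the other 419 IDs it was -1.04 (-1.15 to -0.95; -0.89 and -1.44 in the 2 libraries), which argues against that explanation for most of them and would follow from 1 expressed copy, as a hypothesis; loss of Mo17 reads on the B73 genome stays open.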

How the results depend on the processing

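The exclusion of IDs at 0 in a parent, the term for ambiguous reads, the exclusion of both hybrid libraries numbered 1, another thinning seed and the fit of 2 groups with the replicate block were tests chosen after the data were seen. Of 123 recomputed counts, 55 stayed within 1.5 times the reported one, among them all counts with DESeq2 size factors and with a minimum log2 fold change of 1; the cause of the other changes was not tested unless stated. The log2 fold changes of 14 results for single IDs, those named in the comparisons, kept their direction in all 186 recomputations, and 32 of these no longer passed the threshold. Without a filter, mop1F1 against WTF1 gave 11 IDs, WTF1 and mop1F1 against the mid-parent 12 and 27, WTF1 against B73 1436, and IDs outside both parents 242 (WTF1) and 274 (mop1F1). The filter of 1 CPM in 2 libraries, the fit of the 2 groups alone and that fit with the replicate block left 0 IDs in mop1F1 against WTF1 (edgeR, 408, 170 and 262 at an unadjusted p below 0.05), and B73 against Mo17 alone gave 9334, where the large spread of the hybrids no longer entered. DESeq2 gave 41 (mop1F1 against WTF1), 933 and 1019 (mid-parent), 2527 (WTF1 against B73), 2613 (WTF1 against Mo17), and 525 and 613 outside both parents. The log-scale mid-parent gave 1169 and 1485 IDs.

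The replicate numbers have no stated meaning, and the differences between numbers correlated across IDs at 0.295 between the hybrids and at -0.069 to 0.098 in the other pairs of groups. With the replicate block, mop1F1 against WTF1 had 0 IDs (edgeR, 391 at an unadjusted p below 0.05), WTF1 against B73 528, and 49 (WTF1) and 90 (mop1F1) were outside both parents; the other counts stayed within 1.5 times.

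Without IDs at 0 in both libraries of a parent, B73 against Mo17 gave 1061, WTF1 against B73 272 and against Mo17 270. Outside both parents there were 17 and 46. The fit and its unadjusted p-values were kept, and only the adjustment was repeated over the remaining IDs. Calls at 0 in a parent were removed by construction, and the further fall in the counts came from the repeated adjustment. A term for the 2 libraries rich in ambiguous reads gave 0 (mop1F1 against WTF1), 4010 (B73 against Mo17), 2501 and 1766 (WTF1 against B73 and Mo17), and 465 and 686 outside both parents. Without both hybrid libraries numbered 1, the spread came from the parents alone and the counts rose to 1866 (mop1F1 against WTF1), 9391 and 12223 (mid-parent), 9678 (B73 against Mo17), 8035 and 6692 (WTF1 against B73 and Mo17), and 2850 and 5459 outside both parents; these assume hybrids that vary like parents, which they did not.

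Leaving out 1 library assumed that the lone library varied like the other groups. Counts ranged from 0 (without mop1F1 replicate 2) to 187 (without mop1F1 replicate 1, 12 higher and 175 lower) in mop1F1 against WTF1, 1062 to 1135 in B73 against Mo17, 83 (without B73 replicate 1) to 1023 (without WTF1 replicate 2) in WTF1 against B73, 454 (without Mo17 replicate 1) to 1737 (without WTF1 replicate 2) in WTF1 against Mo17, 4 to 422 for WTF1 outside both parents and 7 to 1086 for mop1F1, with 0 in every mid-parent fit. The list tests were not run. Depth sets the lowest level that can be told from 0, 0.115 to 0.256 CPM per library; its effect on the number of calls was not tested.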

Other observations

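The test of IDs switched on in the mutant was chosen after the data were seen. The hypothesis was that IDs silent in the wild-type hybrid are switched on in mop1F1 more often than they differ between any other 2 pairs of hybrid libraries. With at least 5 CPM in both mop1F1 libraries and under 0.5 CPM in both WTF1 libraries, 4 IDs were found, 3 of them also under 0.5 CPM in all parental libraries. These were Zm00001d025803.RefGen_V4, Zm00001d023656.RefGen_V4, Zm00001d036575.RefGen_V4 and Zm00001d047900.RefGen_V4, named after their values were seen. The opposite, on in WTF1 and off in mop1F1, held for 1 ID, Zm00001d003128.RefGen_V4. The split by replicate number gave 6 IDs in each direction and the crossed split gave 0. The 4 IDs do not exceed what the replicate numbers give, so the hypothesis as worded was not borne out. The libraries numbered 1 and 2 differed in part alike in both hybrids, so the split by number is not a measure of chance. The test therefore cannot decide whether the 4 IDs were switched on with the mutation.

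The 174 gene IDs of the older GRMZM style had no counts in the Mo17 libraries. They had 199 and 106 counts in B73, 433 and 1941 in WTF1, and 1040 and 2071 in mop1F1. The 472 IDs with 0 counts in both B73 libraries and at least 1 CPM in Mo17 had a median log2 ratio of WTF1 to Mo17 of -1.76.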
